A study of Arabidopsis thaliana with 6 samples.

How the data were processed

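Total RNA from the aerial parts of whole Arabidopsis thaliana plants was hybridised, biotin-labelled, to 6 one-colour oligonucleotide arrays. The labels name 3 plant lines: Col-0, sfr2-1 and a line spelled str6-1. Whether str6-1 is a misspelling of sfr6-1, a freezing-sensitive mutant of MED16, is not settled by the labels, so the spelling was kept and the mutated gene of this line is treated as unknown. Each line has 1 array whose title ends in the letter C and 1 whose title ends in W. The labels do not spell out these letters. The series title speaks of cold-induced changes and of freezing-sensitive mutants, while every label gives 8 hour days, 21 to 22 degrees and no treatment at growth stage 1.12. The letters are therefore used as they stand, as C arrays and W arrays.

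The deposited values are probe set intensities on a linear scale, made with MAS5 per the submitters' processing notes. The MAS5 version, the scaling target and the detection calls are not given in the sources used here. MAS5 summarises the perfect-match and mismatch probes of a probe set into 1 signal. In the values themselves, the mean after trimming 2% at each end was 100.0 on each array, so the arrays had been scaled to a common level before deposit. Array medians lay between 38.8 and 43.7. With each array scaled to 1 mean, a large rise of abundant transcripts lowers the values of all others. Very bright probe sets may sit near the upper limit of the scanner, which compresses their differences. No depth exists for arrays, and their number limits the precision.

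The table held 22810 probe sets, of which 64 were control probe sets, left out of the tests. Values were taken as log2(signal + 10), where 10 is the median of all signals divided by 4 and rounded. The added constant understates the change of dim probe sets. The upper 60% of the 22746 remaining probe sets by mean log2 value were kept, 13648 in all, which put the lower limit at a signal of about 26.9. Probe sets were named only through the platform annotation supplied with the values, updated through the gene identifiers of a RefSeq table for assembly TAIR10.1. Of all probe sets, 13513 had 1 gene, 503 had several and 8794 were not listed and stay unnamed here. No gene was named from a probe set with several. Of the kept probe sets, 7363 carried 1 gene, from 7286 loci. A locus number of the form AT1G16850 stands for genes without a symbol in that table. No coordinates are printed, since the sources used here name no genome build.

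The comparison of C with W arrays used limma's lmFit and eBayes with an intensity trend, in an additive model of line and letter over all 6 arrays, two-sided, with Benjamini-Hochberg adjustment over the kept probe sets and a threshold of 0.05. The 3 lines are the repeats of this contrast. The comparisons of sfr2-1 and str6-1 with Col-0 came from the same model, in which the 2 letters are the repeats. The model has 2 residual degrees of freedom, with 5.68 prior degrees of freedom. Nothing in the labels tells of separate cultures, and each line and letter has 1 array, so p-values measure only the spread between these arrays. A difference between lines in the C minus W change has no test and is described by values.

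The model was tested on simulated data with the real means, spreads drawn from the fitted prior, and 200 of 13648 probe sets changed. For C minus W it recovered 13 of 100 probe sets changed 2-fold and 94 of 100 changed 4-fold, with 6 false calls. For str6-1 minus Col-0 it recovered 2 of 100 changed 2-fold and 82 of 100 changed 4-fold, with 4 false calls. The real C minus W contrast called 2383 probe sets, and the adjustment is stricter when fewer change. The simulated recovery may therefore understate that of the real C minus W contrast.

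Before the data were examined, 16 gene lists with 248 genes were fixed, together with the tests, the alternatives and the rule for the genes to name. The lists covered cold-regulated (COR) genes, CBF and early cold transcription factors, abscisic acid and drought response, galactolipid and membrane lipid synthesis, sugar, starch and proline metabolism, flavonoid and anthocyanin synthesis, photosynthesis, the circadian clock, salicylic acid defence, jasmonate and ethylene defence, heat shock, cell wall loosening, senescence, cytosolic ribosomal proteins, and markers of roots and of flowers, pollen and seed. Because most of these genes had no named probe set here, 35 were measured and 26 kept, and only 3 lists had 3 or more kept members. Those 3 were tested with limma's camera at a preset correlation of 0.01, with an estimated correlation and fry as alternatives, using the brightest probe set per gene. Within each line, a list's median change was set against 10000 random lists of equal size matched on mean intensity.

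The naming rule took the 10 highest and 10 lowest C minus W changes past the threshold with 1 sign in all 3 lines. For each mutant it took the 10 higher and 10 lower genes with the largest smaller-of-2 difference from Col-0 over the C pair and the W pair. It also took the 10 higher and 10 lower genes whose C minus W change lay beyond that of both other lines. List members and the control probe sets were added, as were SFR2 and MED16, loci tied by name to freezing-sensitive mutants; these had 0 named probe sets and are not reported. Other genes are said to be chosen after their values were seen. All comparisons were repeated with a smaller pseudocount of 2.56 and a larger one of 41, quantile normalization, median centring, no filter, a filter at 40%, eBayes without trend, a model without the block, and each array or line left out. With line in the model, leaving out either array of a line takes that line out of C minus W, so those alternatives are not separate checks. A mutant was also set against the mean of the other 2 lines, an alternative chosen after seeing the data. Tools were R 4.3.3, limma 3.58.1, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.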

Results

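Transcript levels were measured in the aerial parts of Arabidopsis plants of 3 lines, with 1 C array and 1 W array per line. Col-0 is the wild-type accession. The sfr2-1 and str6-1 lines are, by the series title, freezing-sensitive mutants. Signals reached 4368 to 5131 on 5 arrays and 8984 on the Col-0 W array. Across genes, Spearman correlations between arrays ran from 0.886 to 0.977. The closest pair was Col-0 C and sfr2-1 C, and the Col-0 W array correlated with the others at 0.886 to 0.931. On that array a GAPDH 3' control probe set read 243 while its redesigned version read 1480, a ratio of 0.164 against 0.511 to 0.728 on the other arrays. No pair of arrays shared more than 1.21% identical values.

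The first comparison asked which transcripts differed between the C and W arrays whatever the line. The kept cold-regulated genes, 7 of 21 listed, stood higher on the C arrays. LTI30, a dehydrin, had a signal of 3928 ± 505 (SD, n = 3 lines) on the C arrays and 160 ± 153 on the W arrays, a log2 change of 5.04 (SE 0.46). COR27 averaged 630 ± 160 on C and 17.3 ± 26.6 on W arrays. EXPA8, an expansin that loosens cell walls, went the other way and fell by 4.67 on the log2 scale (SE 0.26), with signals of 12.9 to 22.7 on C and 598 to 932 on W arrays. In limma's test, 1122 of 13648 probe sets were higher and 1261 lower on the C arrays, and all 2383 had 1 sign in the 3 lines. The call itself favours this last outcome, since differences between lines in the change enter its residual spread.

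Among these calls, 758 rose and 703 fell at least 2-fold, and 1262 belonged to a named gene. At an unadjusted p under 0.05, limma gave 4573 probe sets where 682 would be expected by chance. The calls were 47.1% higher as deposited and 61.4% higher after median centring, with 1462 higher and 918 lower; the median change of all kept probe sets was -0.09 and 0.03 respectively. Without the Col-0 W array, 650 were higher and 589 lower, and without the Col-0 C array 654 and 595. Either way the remaining Col-0 array adds nothing to C minus W, so these are the same check and do not tell Col-0 W from Col-0 C. Without the sfr2-1 C or sfr2-1 W array, 764 and 759 were lower, and with no filter 707 were higher and 677 lower.

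The 10 named increases included AT1G16850, at 5.49 (SE 0.35, adjusted p = 0.000326 in limma), with LTI30 and COR27 at adjusted p values of 0.00101 and 0.000908. Several of the 10 had W signals under the added constant of 10, so their order is not fixed: AT1G16850 stood at 6.14 and LTI30 at 5.19 with the smaller pseudocount, but at 4.28 and 4.62 with the larger one. LEA4-5, a late embryogenesis abundant protein gene, rose by 4.77 (SE 0.28), from signals of 1.4 to 4.5 on the W arrays to 215 to 471 on the C arrays. AT2G23910 read 273 to 322 on the C arrays and 1.0 to 3.4 on the W arrays. AT1G11210, AT1G48100, AT1G51090, AT2G16890 and AT4G01870 rose by 4.11 to 4.59. Besides EXPA8, the named decreases were AT1G13650, which fell by 4.18, AT1G51400, which fell by 3.80, AT2G20670, AT2G34620, AT5G19120, AT1G23390, AT5G16030, AT5G44020 and AT3G26510, the last 7 with log2 changes from -3.62 to -3.12. Their adjusted p values were at most 0.00337.

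All 7 kept genes of the 21 on the cold-regulated list rose, and all 7 passed adjusted over the list alone. Besides LTI30 and COR27 these were COR47, another dehydrin (3.10, SE 0.30), COR28 (3.22, SE 0.28), COR15A and COR15B, which encode chloroplast proteins that protect membranes in the cold (2.53, SE 0.35, and 2.38, SE 0.42), and TIL, a lipocalin (1.07, SE 0.20). The Col-0 W and str6-1 W signals of COR28 lay under the added constant. Its change was 3.94 with the smaller pseudocount and 2.06 with the larger one. The list's median change was 3.10, with a camera adjusted p = 8.19e-09. With an estimated correlation the adjusted p = 0.182, in a range of 5.43e-18 to 0.182 over the alternatives, and fry gave 0.0353. COR15B missed the threshold without the Col-0 C or the Col-0 W array, its adjusted p in limma running from 9.71e-06 to 0.0681.

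Of the 6 kept flavonoid and anthocyanin genes among 21 listed, 5 rose, and 6 passed adjusted over the list alone. UGT78D2, a flavonoid glucosyltransferase, rose by 3.03 (SE 0.26), from a range of 62 to 128 on W arrays to 804 to 899 on C arrays. UGT79B1, an anthocyanin glycosyltransferase, rose by 2.16 (SE 0.20), and DFR, which encodes dihydroflavonol reductase, by 1.33 (SE 0.23). UGT75C1 and 5MAT rose by 0.98 and 0.97. UGT78D1 was at 0.76 (SE 0.30, adjusted p = 0.127). The list's median was 1.15, and 1.74 with the stricter filter, which kept fewer members; camera gave an adjusted p = 2.41e-06; with an estimated correlation the adjusted p = 0.117, in a range of 4.33e-08 to 0.117, and fry gave 0.00402. The calls of UGT75C1, lost with no filter and without an array of Col-0 or str6-1, and of 5MAT, lost with no filter and without an array of sfr2-1, had adjusted p values in limma of up to 0.0891 and 0.0567; UGT78D1 passed without an array of str6-1.

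Photosynthesis genes were lower on the C arrays in 2 of 4 kept members, and 3 passed adjusted over the list alone. LHCB4.2, a light-harvesting antenna protein of photosystem II, fell by 1.99 (SE 0.22), and LHCB4.1 fell by 0.70 (SE 0.20, adjusted p = 0.0481). PRK, of the Calvin cycle, had a change of -0.56 (SE 0.21, adjusted p = 0.108) and RCA, Rubisco activase, one of -0.43 (SE 0.19, adjusted p = 0.158). The list's median was -0.63, with a camera adjusted p = 0.0114; with an estimated correlation the adjusted p = 0.300, in a range of 0.00164 to 0.300, and fry gave 0.0478. The LHCB4.1 call held under only 5 of 17 alternatives and was lost with the smaller pseudocount, quantile normalization, median centring, no filter, eBayes without trend, no line block, and without an array or the pair of Col-0 or sfr2-1, its adjusted p in limma running from 0.0131 to 0.209; PRK passed without an array of str6-1.

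The other lists had at most 2 kept members and no set test. ZAT10, a zinc finger repressor on the early cold list, rose by 1.76 (SE 0.20), and GI, a clock gene, by 1.99 (SE 0.34). SPS4F, a sucrose phosphate synthase, had a change of 1.21 (SE 0.36, adjusted p = 0.0578), and the expansin gene EXPA4 one of -0.88 (SE 0.27, adjusted p = 0.0650). GI missed the threshold without an array of Col-0, SPS4F passed under median centring and without an array of sfr2-1 or str6-1, and EXPA4 passed without an array of str6-1. WRKY53 and GRXC9, on the salicylic acid list, were at 0.38 and -0.06, and the ribosomal protein genes RPL4A and RPL4D at 0.20 and 0.11, none past the threshold. The sign for GRXC9 turned under median centring and quantile normalization and without an array of str6-1, and that for RPL4D without an array of Col-0. The measured members of the heat shock, jasmonate and root lists lay below the intensity filter. The abscisic acid, galactolipid, senescence and flower lists had no measured member.

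**Figure D1:**
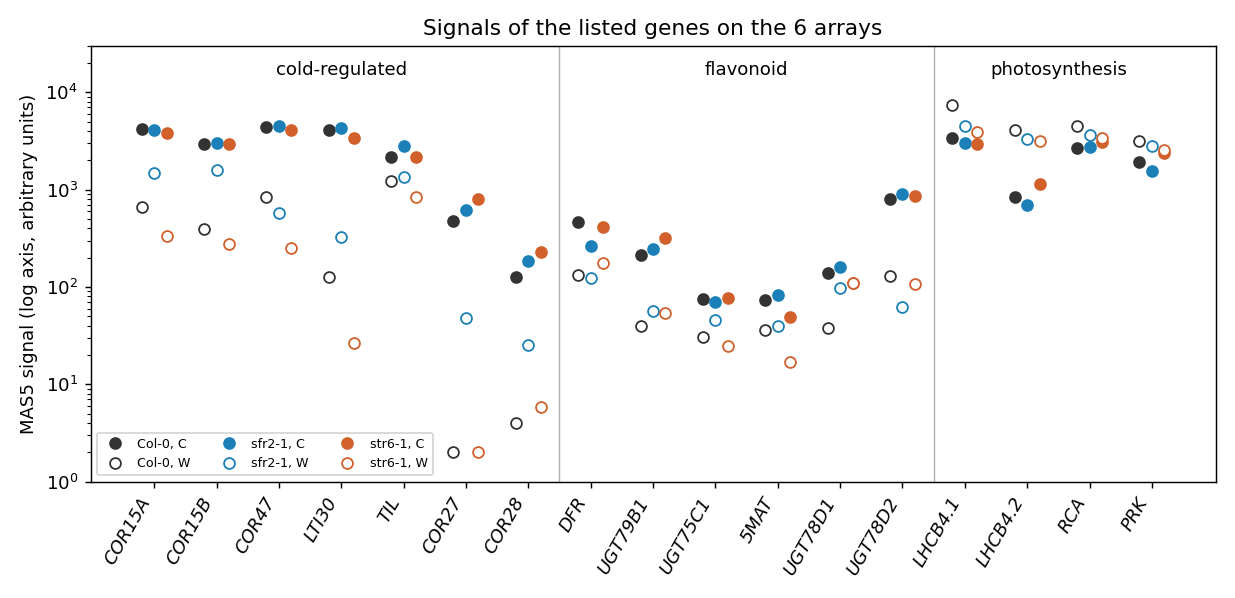
MAS5 signal of each kept gene of the 3 tested lists on the 6 arrays, on a log axis in arbitrary units; filled circles are C arrays, open circles W arrays, and colours the lines, 1 array each. All 7 cold-regulated genes lie higher on the C array than on the W array of every line, and LHCB4.2 lies lower.

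Whether the lines shared these changes was described from each line's pair of arrays. Pearson correlations of the changes across genes were 0.671 between Col-0 and sfr2-1, 0.615 between Col-0 and str6-1 and 0.671 between sfr2-1 and str6-1. Spearman correlations were 0.582, 0.506 and 0.594 in the same order. Genes are not independent replicates. Of the probe sets that changed at least 2-fold in both Col-0 and str6-1, 996 went the same way and 28 opposite ways. The corresponding numbers were 1081 and 19 for Col-0 and sfr2-1, and 943 and 27 for the mutants. The cold-regulated list's median change was 2.85 in Col-0, 2.46 in sfr2-1 and 3.91 in str6-1, each above all 10000 matched random lists, which take genes as independent. The W signals of several members were lowest in str6-1, where LTI30 read 26.3 against 127 in Col-0 W and 327 in sfr2-1 W, and COR47 249 against 831 and 581. On the C arrays alone, COR15A read 4169, 4100 and 3850 in Col-0, sfr2-1 and str6-1, and COR47 4442, 4484 and 4066. The flavonoid medians were 1.69, 0.98 and 1.26 in the same order, at percentiles of 99.87 or higher. The photosynthesis medians were -0.94, -0.72 and -0.26, at percentiles of 0.77, 3.96 and 12.6; under quantile normalization they were -0.45, -0.58 and -0.30, so that the order of Col-0 and sfr2-1 turned.

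**Figure D2:**
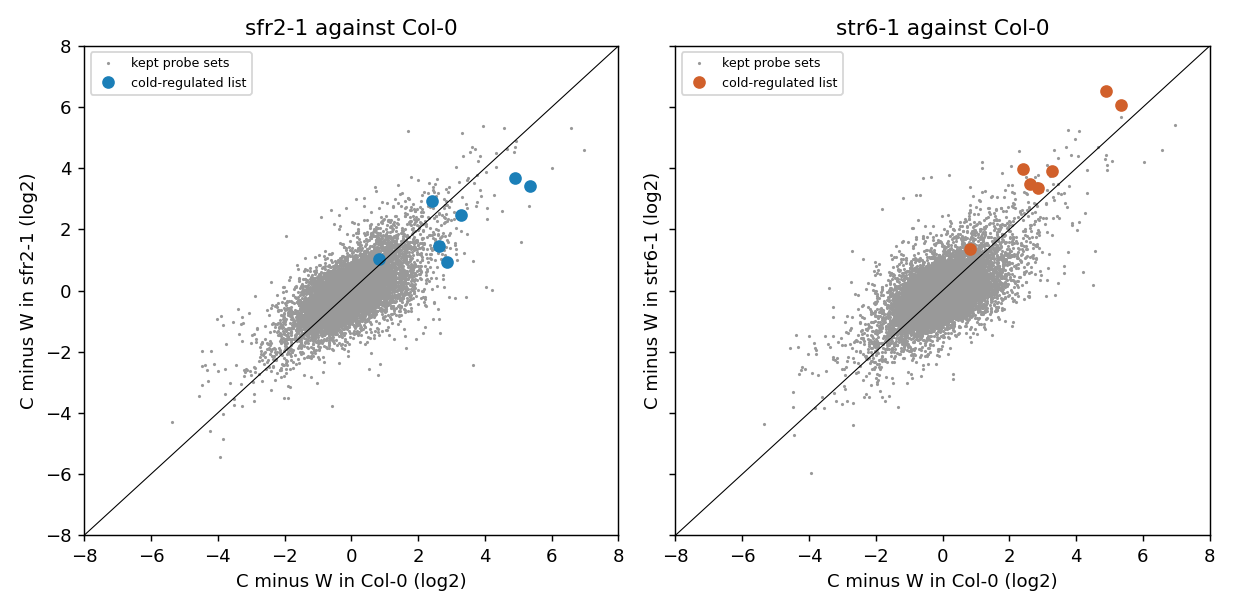
C minus W log2 change of each kept probe set in a mutant against that in Col-0; the line marks equal changes, and large circles are the 7 cold-regulated genes. Pearson correlations across genes are 0.671 for sfr2-1 and 0.615 for str6-1.

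A subset of genes that rose on the C arrays reached lower levels on the str6-1 C array than on both other C arrays. AT3G14890 read 575 in Col-0 C, 594 in sfr2-1 C and 80.6 in str6-1 C, against 61.5 to 80.7 on the W arrays. WSD1, a wax ester synthase gene, read 174, 210 and 10.3 on the C arrays of Col-0, sfr2-1 and str6-1. AT1G16850 read 1369, 1963 and 433, and AT1G51090 read 1199, 1504 and 519. Among the 1122 probe sets higher on C arrays, 59 were at least 2-fold lower on the str6-1 C array than on both others, against 3 for Col-0 and 0 for sfr2-1. The str6-1 C array also lay furthest from the other C arrays over all kept probe sets, with an SD of the log2 difference of 0.46 from Col-0 C and 0.44 from sfr2-1 C, against 0.32 between these; 558 probe sets differed at least 2-fold between str6-1 C and Col-0 C, and 103 between sfr2-1 C and Col-0 C. Of the 59, 31 had a named gene; chosen after their values were seen, they included the zinc finger gene GIS (169, 167 and 38.7), the serpin gene SERPIN1 (1040, 1175 and 394), the cystatin gene CYS1 (1030, 1008 and 439) and CCT2, of phosphatidylcholine synthesis (285, 346 and 80.7).

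Among the 1261 probe sets lower on C arrays, 29 stayed at least 2-fold higher on the str6-1 C array than on both others, against 4 for Col-0 and 0 for sfr2-1. By the lower of the signals on the other C arrays, the 59 included 0 of 20 increased probe sets above 2500, 11 of 67 from 1000 up to there, 43 of 781 from 100 and 5 of 254 below. The difference between lines was not tested. The 59 became 28 with the Col-0 W or the Col-0 C array left out of the model that made the calls, 98 with str6-1 C or str6-1 W left out, and 36 with no filter.

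**Figure D3:**
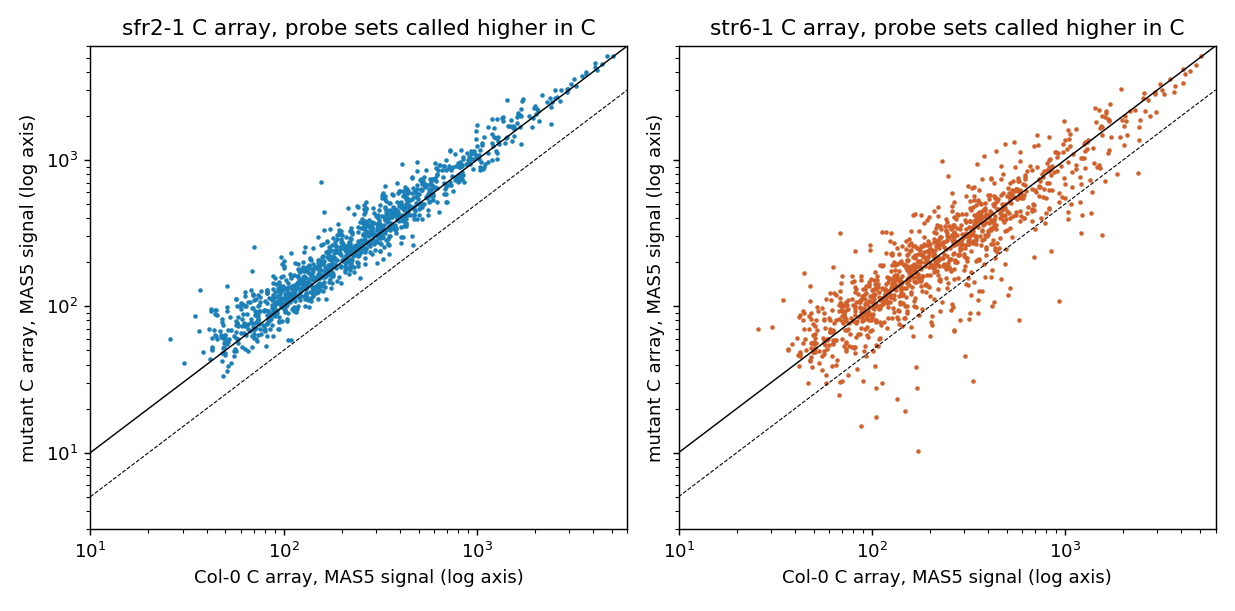
Signals of the 1122 probe sets called higher on C arrays, mutant C array against Col-0 C array, both axes logarithmic and in arbitrary units; the solid line marks equal signals and the dashed line 2-fold lower. In str6-1, 59 probe sets are at least 2-fold lower than in both other lines, against 0 in sfr2-1.

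Some genes that rose on the C arrays had higher signals on the sfr2-1 W array than on both other W arrays. COR15B read 1584 on the sfr2-1 W array against 396 in Col-0 W and 275 in str6-1 W, and COR27 read 48.0 against 2.0 on each of the others. AT1G11210 read 115 against 8.6 and 4.3, and GI 385 against 165 and 80.7. Of the 1122 increased probe sets, 54 were at least 2-fold higher on the sfr2-1 W array than on both other W arrays, against 10 for Col-0 and 8 for str6-1. In the other direction, 36 were at least 2-fold lower on the Col-0 W array than on both others, 26 on str6-1 W and 10 on sfr2-1 W. Over all kept probe sets the Col-0 W array lay furthest from the other W arrays, with an SD of the log2 difference of 0.60 from sfr2-1 W and 0.57 from str6-1 W, against 0.47 between these. The 54 became 30 with the Col-0 C or Col-0 W array left out of the model, 35 with the larger pseudocount and 81 with sfr2-1 C or sfr2-1 W left out.

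The comparison of str6-1 with Col-0 asked which transcripts differed between these lines on both letters. AT5G62360 and AT3G53980 were the 2 probe sets past the threshold, both lower in str6-1. AT5G62360 read 109 in str6-1 C and 1.7 in str6-1 W against 927 and 148 in Col-0, a log2 difference of -3.37 (SE 0.31). AT3G53980 read 3.3 and 3.1 against 102 and 72.5, a difference of -2.86 (SE 0.25). The str6-1 signals of AT3G53980 and the str6-1 W signal of AT5G62360 lay under the added constant, which sets the size of these differences: with the smaller and the larger pseudocount they were -3.94 and -1.53 for AT3G53980, and -4.10 and -2.42 for AT5G62360. In sfr2-1 these genes read 1015 and 204, and 65.6 and 51.4. Both had an adjusted p = 0.0451 in limma, with 784 probe sets at an unadjusted p under 0.05 where 682 would be expected.

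Among named genes below the threshold, ATSBT5.2, a subtilisin-like protease gene, read 10.2 and 14.2 in str6-1 C and W against 80.7 and 98.9 in Col-0 and 90.4 and 186 in sfr2-1 (difference -2.17, SE 0.27, adjusted p = 0.231). AT2G04570, AT1G71000, EXLB1, AT5G05960, AT4G32800, AT5G33370 and WSD1 were also at least 2-fold lower in both pairs. On the sfr2-1 W array AT4G32800, AT1G71000, AT5G33370 and WSD1 read 10.9, 5.9, 91.8 and 15.4. These values lay nearer to str6-1 W, at 9.5, 3.3, 69.8 and 8.6, than to Col-0 W. Their W differences are thus not particular to str6-1. The sfr2-1 W signals of AT2G04570, EXLB1 and AT5G05960, at 80.3, 85 and 300, lay nearer to Col-0 W. AT1G47400 read 322 and 80.3 in str6-1 against 61.9 and 29.7 in Col-0, and MT1C, a metallothionein gene, 1147 and 364.5 against 437 and 143. In sfr2-1 AT1G47400 read 36.4 and 34.3, and MT1C 632 and 538. The W signal of MT1C was thus higher in sfr2-1 than in str6-1, and only its C signal set str6-1 above both other lines. In all, 40 probe sets were at least 2-fold lower and 16 higher in str6-1 in both pairs, while 38 went opposite ways. The 2 calls fell to 1 with the smaller pseudocount, and to 0 with the larger pseudocount, quantile normalization, no filter, the stricter filter and no letter block. Without sfr2-1 C there were 4 calls. With an array of str6-1 or Col-0 left out, that line rests on 1 array and adds nothing to the residual spread, so calls of those fits are not given.

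For sfr2-1 against Col-0, no probe set passed. In limma, 591 probe sets had an unadjusted p under 0.05 where 682 would be expected, and the lowest adjusted p was 0.913. The named differences of 1 sign in both pairs included lower values of AT3G11290, at 8.2 and 9.9 in sfr2-1 C and W against 40.9 and 94.3 in Col-0, and higher values of AT2G35390, at 67.3 and 41.7 against 17.5 and 11.5. AT2G35390 was also higher in str6-1, at 58.0 and 50.8, a comparison that shares the Col-0 arrays. The plastid genes psbA and psbE, of photosystem II, read 1507 and 778, and 570 and 725, in sfr2-1 against 2953 and 2955, and 1111 and 1836.5, in Col-0. In str6-1 psbA read 1521 on C and 3236 on W, so only its W value set sfr2-1 apart from both other lines. PDC2, a pyruvate decarboxylase gene, read 486 and 344.5 against 239 and 122. On the W arrays psbA and psbE do not stand for plastid transcripts as a group. Over 69 plastid-encoded probe sets, the median deviation from their means was 0.29 on sfr2-1 W and -0.66 on Col-0 W. On the C arrays it was -0.12 in sfr2-1 and 0.02 in Col-0. Only 9 probe sets differed at least 2-fold the same way in both pairs and 16 opposite ways. Without the str6-1 C array 3 probe sets passed. With an array of sfr2-1 or Col-0 left out, that line rests on 1 array and adds nothing to the residual spread, so calls of those fits are not given.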

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

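The tests of the Col-0 W array and of plastid transcripts were fixed before their results were seen, and that of a mixed sfr2-1 W sample was chosen after. Of 91 named probe sets, 9 had C minus W changes of at least 1 log2 unit in a mutant and, with the opposite sign, in Col-0. These differences were not tested, since each line and letter has 1 array.

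In sfr2-1 all 6 such genes were plastid-encoded. The sfr2-1 change less that of Col-0 was -2.48 for ndhF, -3.10 for petG, -3.50 for rps14, -2.86 for petD, -3.53 for atpI and -2.58 for rpl20. For rps14 the change was -1.87 in sfr2-1, 1.63 in Col-0 and 1.17 in str6-1. In str6-1 the difference from Col-0 was 2.62 for AT2G07722, 4.203 for AT1G05340 and -3.13 for AT5G44580. AT1G05340 read 252 on the str6-1 C array and 22.5 to 70.5 on the others.

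The plastid pattern was wider than the named genes. Over 69 plastid-encoded probe sets the median change was 0.75 in Col-0, -0.31 in sfr2-1 and 0.44 in str6-1, with the same signs under quantile normalization and median centring, and 56 of them lay lower in sfr2-1 than in both other lines; none of the 69 passed in limma over the 3 lines. One candidate explanation is unequal capture of RNA without poly(A) tails, which would move the 12 mitochondrial probe sets alike: their gap was 0.269 times the plastid gap against Col-0 (the smaller of the ratios; 95% bootstrap interval -0.29 to 0.51) and 1.00 times against str6-1, which leaves it open. Several mitochondrial probe sets were dim, such as nad5 at 19.9 to 41.2, and nad1 had more than 1. The added constant shrinks the changes of such dim probe sets, which limits these ratios. A low Col-0 W reading adds to the gap against Col-0 but not to that against str6-1, since the median deviation of plastid probe sets from their means was -0.66 on the Col-0 W array, 0.29 on sfr2-1 W and 0.54 on str6-1 C. A change of plastid transcripts in sfr2-1 plants stays open and untested; SFR2 is known as a galactolipid-remodelling enzyme of the chloroplast envelope.

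The Col-0 W array stood apart in its correlations, its control probe sets and its highest signal. Besides GAPDH, this held for the non-plant controls cre and bioD. The older over the redesigned 3' probe set of cre gave 0.33 there against 0.56 to 0.64 elsewhere. For bioD the ratio was 2.02 against 0.78 to 0.97. A defect that moves single probe sets would make probe sets of 1 gene disagree on that array. Over 53 genes with 2 or more kept probe sets, the median disagreement was 0.59 log2 units on Col-0 W and at most 0.31 on the others, a ratio of 1.89 (95% bootstrap interval 1.51 to 2.74). This is consistent with such a defect, found after the control probe sets had been seen; no biological explanation was tested. Values that rest on Col-0 W alone, such as W differences of the mutants from Col-0, carry this limit.

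On the sfr2-1 W array, probe sets of the C minus W response lay part of the way from W to C: over the 500 probe sets with the largest changes in Col-0, those higher on C arrays lay 0.26 of the way, and those lower 0.17 of the way, on the str6-1 axis; on the Col-0 axis, over the 500 of str6-1, the places were 0.20 and 0.28. Mixed-in RNA of C plants would move the higher ones far more: on the str6-1 axis a share of 6.42% matched to them puts the lower ones at 0.04, whereas these lay 0.131 beyond it (95% bootstrap interval 0.07 to 0.19, over probe sets only), and 0.25 beyond it on the other axis; as both sets also parted by 0.104 and 0.101 when Col-0 W and str6-1 W were placed on each other's axes, this is not clearly beyond the spread between arrays, and mixing stays open. This was the last of 3 criteria, the earlier ones replaced, and the spread between arrays added, after their results were seen: the first set 5 probe sets near 0 on the other W arrays against the lowest cold-regulated share, that of COR47, and did not exclude mixing, since only LEA4-5 lay far under it; of the 5, LEA4-5, AT2G23910 and AT1G16850 had C shares of -0.31%, 0.67% and 1.71%, COR27 7.50% and AT1G11210 12.9%, against 5.87% to 46.0% for the 6 cold-regulated genes besides COR47. The next, cold-regulated shares from 1.04% to 46.0%, counted against it but rested on COR47, whose W signals were already high. A milder exposure or another hour of harvest may have moved this sample, and a property of sfr2-1 stays open too; 1 array tests none of these. Ratios of 3' to 5' control signals, a check of RNA quality, were highest on sfr2-1 W for some pairs. These were redesigned actin (3.25 against 1.60 to 2.56 elsewhere), older GAPDH (2.27 against 0.60 to 1.68) and older ubiquitin (3.52 against 1.49 to 3.30). Redesigned GAPDH (1.08), redesigned ubiquitin (2.35) and older actin (5.84) were not highest there. Whether RNA quality moved this sample was not tested.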

How the results depend on the processing

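Over the alternatives that kept them, no direction turned among the 20 genes named by rule in each of the 3 comparisons or the medians of the 3 tested lists, nor, under the pseudocounts, scalings and filters, among the genes named for a mutant's change apart from both other lines. For each mutant the naming rule asked for 1 sign in both pairs, which favours this outcome. For C minus W it asked for 1 sign in all 3 lines, so only the scalings could have turned these directions. Of the other kept list members, those of GRXC9 and RPL4D, not past the threshold, turned: GRXC9 to 0.073 under quantile normalization, 0.063 under median centring and 0.14 without an array of str6-1, from -0.29 to 0.14 over the arrays left out, and RPL4D to -0.086 without an array of Col-0, from -0.086 to 0.23 over the arrays left out. Genes chosen after their values were seen were not followed. All alternatives were planned except setting a mutant against the mean of the other 2 lines, chosen after seeing the data. The 20 named C minus W genes passed under each setting that kept them. Counts moved with fewer arrays or more dim probe sets tested. Leaving out an array or a line gave 650 to 1222 higher and 589 to 1265 lower probe sets, with Col-0 arrays lowering them most, and no filter gave 707 and 677. The balance of calls, 1122 higher and 1261 lower, turned to more higher with no filter, median centring (1462 and 918), quantile normalization (1203 and 1063), the stricter filter (962 and 941), and without an array of Col-0 or sfr2-1; median centring shared 2040 of the 2383 calls. With 1 residual degree of freedom, a lone array is then assumed to vary like the others. The str6-1 calls numbered 1 with the smaller pseudocount, 0 with the larger one, quantile normalization, no filter, the stricter filter and no letter block, 3 against the mean of the other 2 lines, and 0 to 113 with an array left out; the cause was not tested. The sfr2-1 calls ran from 0 to 47 with an array left out. Probe sets lower on str6-1 C than both other C arrays numbered 36 with no filter and 28 to 98 with an array left out. Those higher on sfr2-1 W numbered 35 with the larger pseudocount and 30 to 81 with an array left out. With an estimated correlation the adjusted p was 0.182 for the cold-regulated median of 3.10, 0.117 for the flavonoid median of 1.15 and 0.300 for the photosynthesis median of -0.63. The Col-0 photosynthesis median moved to -0.45 under quantile normalization, above the -0.58 of sfr2-1, and the stricter filter, with fewer members, gave flavonoid medians of 1.74 over the 3 lines, 1.49 in sfr2-1 and 1.79 in str6-1. The line term of the model pairs the C and W arrays of each line; without it 1180 were higher and 1418 lower. Detection calls were not used here, so probe sets near a signal of 10 have uncertain folds.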

Other observations

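The tests of splits, of the meaning of C and of cuticle genes were fixed before their results were seen. Among the genes named by rule, several had a C minus W change in str6-1 apart from that of both other lines. ATGP4 read 426, 372 and 163 on the C arrays of Col-0, sfr2-1 and str6-1, and 134, 140 and 240 on the W arrays. AT2G43620 read 398, 512 and 19.7 on the C arrays and 116, 4.0 and 47.1 on the W arrays; its change also stood apart in sfr2-1, at 5.22 against 1.69 in Col-0 and -0.94 in str6-1, so it is not particular to 1 line. In the other direction AT3G62550 read 432 on Col-0 C, 431 on sfr2-1 C and 1326 on str6-1 C, against 801, 920 and 314 on the W arrays, and the plastid gene rpoB read 253 on str6-1 C and 20.3 to 125 on the other arrays. None of these differences was tested.

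Over the 500 probe sets with the largest changes in sfr2-1, the str6-1 C array lay 0.84 of the way from Col-0 W to Col-0 C. On the sfr2-1 axis, over the 500 of Col-0, it lay at 0.77. The sfr2-1 C array lay at 1.13 on the Col-0 axis and 1.23 on the str6-1 axis. The Col-0 C array lay at 0.85 on the sfr2-1 axis and 1.18 on the str6-1 axis. A place below 1 on 1 axis was thus not particular to str6-1, but only the str6-1 C array lay below 1 on both. On the same Col-0 and sfr2-1 axes the str6-1 W array lay at -0.06 and -0.22, so its low C places went with low W places. The sfr2-1 W array lay at 0.23 on the Col-0 axis and 0.22 on the str6-1 axis. Col-0 W lay at -0.26 on the sfr2-1 axis and 0.07 on the str6-1 axis. The C places alone therefore do not show a shorter way from W to C in str6-1. For the cold-regulated list, the change on these arrays was not smaller in str6-1, with medians of 3.91 there and 2.85 in Col-0. Each kept member changed more in str6-1 than in both other lines, with 1 pair of arrays per line. Whether the response of str6-1 plants is smaller stays undecided. The difference between lines has no test, and the W signals of COR15A, COR15B, COR47 and LTI30 were lowest in str6-1. On the C arrays COR15A, COR47 and LTI30 read 3364 to 4484, where the highest signals were 5062 to 5131, and COR15B 2913 to 3047; whether such signals are compressed was not tested. Of the dimmer members, COR27 read 797 on str6-1 C against 478 on Col-0 C, COR28 228 against 126 and TIL 2163 against 2179.

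A hypothesis fixed beforehand was that C marks plants given cold, under which the cold-regulated genes would rise by over 1 log2 unit in Col-0 and stand apart from random lists. Their median change there was 2.85, above all 10000 random lists, which is consistent with cold on the C arrays. Random lists take genes as independent; over the 3 lines, with an estimated correlation, the list's adjusted p = 0.182, in a range of 5.43e-18 to 0.182 over the alternatives. The letters remain unexplained by the labels, which give 21 to 22 degrees for every sample.

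Of the 10 ways to divide the 6 arrays into 3 and 3, the real one called 2383 probe sets and the highest of the others 0, with line kept in the model. The others are no like comparison: 6 of them rest on 1 line's pair of arrays, and in the remaining 3 the C minus W change enters the residual spread, which keeps their counts low by construction. With 10 divisions the share cannot fall under 0.05.

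The lower WSD1 signals in str6-1, with those of AT5G33370, prompted a list of 42 other cuticle genes, to see whether this group was lower as a whole. Only CER26 and FATB were kept. Their median str6-1 minus Col-0 difference was 0.605 in the C pair and -0.69 in the W pair, and 2 genes are too few to decide.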
